A study of Aspergillus niger with 16 samples.

How the data were processed

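Total RNA from mycelium of the filamentous fungus Aspergillus niger was sequenced in 16 libraries made with Illumina protocols. They fall into 8 groups of 2: a reference strain and a strain lacking *gaaR* (ΔgaaR), each on D-galacturonic acid (GA) for 2 h and on sugar beet pectin (SBP) for 2, 8 and 24 h. Groups and replicate numbers were taken from the sample labels. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

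Each deposited file held, per the file headers, an RSEM expected count and an FPKM value per gene for 1 library, together with a gene length. The submitters' processing notes name BWA, Bowtie2 and RSEM, without versions or the role of each. The expected counts were deposited by the authors without normalization and need not be whole, and 548 of 168277 listed values (0.3%) were not. The FPKM values were deposited by the authors as read numbers scaled by gene length and by library total. The lengths were multiples of 3 for 100% of genes and are therefore coding lengths. A gene was listed only where its count was above 0, so an unlisted gene was taken as 0 reads. Total expected counts ranged from 3203011 to 4574019 per library, with 10245 to 10857 genes listed, 11580 in any library and 9057 in every library.

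Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided). Libraries were scaled by TMM, and filterByExpr with default settings left 10003 genes. All 16 libraries entered 1 fit with 1 mean per group, which left 8 residual degrees of freedom, a common dispersion of 0.041 and 7.8 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this test unless another tool is named, and a log2 fold change is followed by its standard error (SE). Levels are mean FPKM ± SD of 2 libraries. Differences of the deletion effect between conditions were tested as interaction contrasts. Gene lists were tested with camera (limma 3.58.1) with the correlation preset at 0.01 and again with an estimated correlation, and with fry. Overlaps of calls were tested with Fisher's exact test, two-sided, over the genes tested. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps.

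The gene identifiers carry NRRL3 locus tags, and no table used here pairs them with gene names. For 23 genes the tag was written down from published knowledge before the data were examined. They are *gaaA* NRRL3_05650, *gaaB* NRRL3_06890, *gaaC* NRRL3_05649, *gaaD* NRRL3_10050, *gatA* NRRL3_00958, *gaaR* NRRL3_08195, *gaaX* NRRL3_08194, *pgaI* NRRL3_02571, *pgaC* NRRL3_08805, *pgaE* NRRL3_02835, *pgaX* NRRL3_03144, *pgxB* NRRL3_08281, *pgxC* NRRL3_05260, *pelA* NRRL3_00965, *pmeA* NRRL3_08325, *pmeC* NRRL3_07470, *rgxB* NRRL3_08631, *xghA* NRRL3_07469, *rglA* NRRL3_00684, *abfC* NRRL3_10865, *abnC* NRRL3_05407, *lacB* NRRL3_02479 and *lacC* NRRL3_11738. These names were recalled and not looked up. They were checked against the RefSeq gene table of another strain (assembly ASM285v2). Of pairs of genes on 5 contigs, 21 of 21 followed the order of the tags, in the same or the reverse direction per contig. The genomic span was shorter than the coding length for 1 gene, *gaaC*. For 3 of 3 pairs with adjacent tags, the locus tags recalled for the other strain were consecutive too, a check that does not use the positions in that table. The knowledge behind the names comes largely from publications on this regulator, so the lists are not independent evidence of direction. Of 136 members of 14 lists fixed beforehand, 113 had no tag and were not analysed here. Only the GA list was whole (5 of 5). The others tested were partial, with 9 of 20 homogalacturonan enzymes, 3 of 15 rhamnogalacturonan and xylogalacturonan enzymes and 4 of 11 side chain enzymes, and 2 of 12 regulators had a tag. Counts and list tests cover these members only. The lack of tags left 9 lists out altogether: pentose catabolism; xylan, cellulose and xyloglucan enzymes; starch, sucrose and inulin enzymes; glycolysis and gluconeogenesis; glyoxylate cycle and organic acids; carbon limitation; conidiation; secretory stress; and the housekeeping control. The conidiation list was the marker list for another cell type, so that check was not made.

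The genes named were fixed by a rule written before the data were examined. It takes *gaaR* in every library and *gaaX*, all 5 GA genes, and up to 4 called members of each other list with the largest absolute log2 fold change in that comparison. It adds the 10 highest and 10 lowest called genes of each deletion comparison with a mean of at least 10 FPKM and at least a 2-fold change. Of the latter, only genes with a name are named, the rest being given as counts. Where both groups lie at or below 3 reads no fold is given, and a gene at 0 in both libraries of a group has a lower bound from a floor of 3 reads per library. Floors and 95% exact intervals cover counting error only.

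The pipeline was tested on simulated counts for 10003 genes. In each deletion comparison 100 genes were changed 2-fold and 109 were changed 8-fold. This is far fewer than the 14.6% to 49.7% of genes called in the data. Recovery and false calls may therefore differ in the data, and scaling with so many changed genes was not simulated. Genes changed 8-fold were recovered at 99.1% on GA, 99.1% on SBP at 2 h, and 100% on SBP at 8 and 24 h. For 2-fold changes the shares were 39%, 44%, 33% and 46%. False calls made up 6.4%, 6.7%, 5.3% and 8.3% of calls in those 4 comparisons. In the simulated interaction of SBP with GA at 2 h, 98% of 8-fold and 6% of 2-fold differences were recovered, with 8.8% false calls.

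Alternatives fixed before the data were examined were an added 2-fold threshold, DESeq2 size factors, total count scaling, no low count filter, a filter of 10 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of only the libraries compared, the replicate number as a block, and each library left out in turn. A fit without the 2 h deletion libraries that held most *gaaR* reads was added after seeing the data. With TMM the median log2 fold change of all genes was -0.12 for the difference of the deletion effect between 24 and 2 h and nearer to 0 in the other comparisons. Under total count scaling it moved to 0.20 for the deletion on GA, 0.18 for the deletion on SBP at 24 h, and 0.27 and 0.32 for 24 h against 2 h in the reference and deletion strains.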

Results

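Transcript levels were measured in Aspergillus niger, an industrial fungus that degrades plant cell walls, with and without *gaaR*, the gene of a transcriptional activator of D-galacturonic acid (GA) use. GA is the main sugar of the pectin backbone. Mycelium was grown for 16 h in complete medium with 2% fructose and moved to minimal medium of pH 6 at 30 °C and 250 rpm, with 25 mM GA for 2 h or 1% sugar beet pectin (SBP) for 2, 8 or 24 h. Each of the 8 combinations of strain and condition had 2 libraries. Total counts lay between 3203011 and 4574019 reads per library. Replicates correlated at 0.9617 to 0.9841 across genes on the log2 scale, and every pair differed by more than sampling noise (chi-square per degree of freedom of 6.02 to 38.15). The 2 libraries of the deletion strain lay further apart than those of the reference strain at 2 h: 624 of 7053 genes (8.8%) were over 2-fold apart on GA and 714 (10.1%) on SBP, against 139 and 107 in the reference.

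The deleted gene was examined first. In the reference strain *gaaR* had 176 and 241 reads on GA, 1959 and 1984 on SBP at 2 h, and 832 and 984 at 24 h; at 8 h its level was 58.2 and 62.9 FPKM. In the deletion strain it had 30 and 1 reads on GA, 0 and 12 on SBP at 2 h, 24 and 24 at 8 h (3.01 and 2.69 FPKM), and 0 and 0 at 24 h. Of the 8 deletion libraries 3 held 0 reads, and each of the 8 lay below both reference libraries of its condition. The log2 fold change of *gaaR* was -3.95 (SE 0.64, adjusted p = 0.00011) on GA, -8.40 (SE 0.74, adjusted p = 3.6e-06) on SBP at 2 h and -4.40 (SE 0.61, adjusted p = 3.4e-05) at 8 h. At 24 h it was at least 280.9-fold lower, from the floor of 3 reads per library. The size moved with single deletion libraries: on GA it was -7.79 without replicate 1 and -2.99 without replicate 2, and on SBP at 2 h -7.43 without replicate 1, while without replicate 2 no *gaaR* read was left there. Its neighbour *gaaX*, the gene of a repressor of the same pathway, fell from 381 ± 26.7 to 20.4 ± 7.16 FPKM on GA (n = 2 each).

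**Figure D1:**
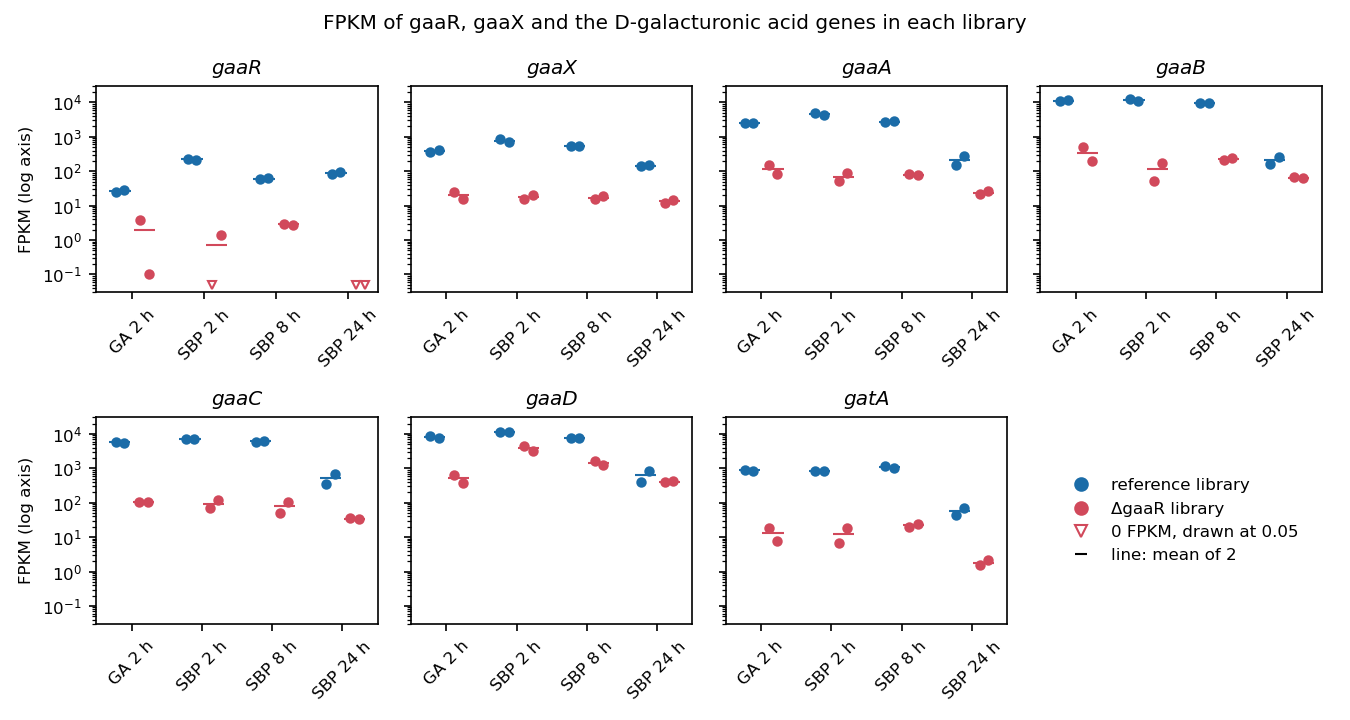
FPKM on a log axis of *gaaR*, *gaaX* and the 5 GA genes in each of the 16 libraries, by strain and condition. Points are single libraries, lines are means of 2, and open triangles mark 0 FPKM; on SBP at 24 h *gaaD* had 621 ± 319 FPKM in the reference and 409 ± 7.75 in the deletion strain.

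Which transcripts depended on *gaaR* with GA as the carbon source was asked at 2 h. All 5 genes of GA uptake and catabolism were lower in the deletion strain. The transporter gene *gatA* fell from 888 ± 48 to 13.3 ± 7.72 FPKM (log2 fold change -6.21, SE 0.42, adjusted p = 1.1e-08). The aldolase gene *gaaC* changed by -5.83 (SE 0.42), the dehydratase gene *gaaB* by -5.20 (SE 0.48), the reductase gene *gaaA* by -4.60 (SE 0.34) and the L-glyceraldehyde reductase gene *gaaD* by -4.13 (SE 0.37). Of 9 enzymes of the homogalacturonan backbone analysed, from a list of 20, 8 were lower and 0 higher, among them the exopolygalacturonase genes *pgaX* (-5.09, SE 0.89), *pgxC* (-4.79, SE 0.37) and *pgxB* (-4.27, SE 0.81). The pectin methylesterase gene *pmeA* had 3 reads against 45, a ratio of 16.5 (95% interval 5.29 to 82.9). Side chain enzymes, with 4 of 11 on the list analysed, went both ways: the β-galactosidase genes *lacB* (-1.82, SE 0.28) and *lacC* (-1.81, SE 0.29) and the arabinofuranosidase gene *abfC* (-1.74, SE 0.27) fell, while the endoarabinanase gene *abnC* rose from 103 ± 11.5 to 1986 ± 984 FPKM (4.22, SE 0.44). Of 3 rhamnogalacturonan and xylogalacturonan enzymes analysed, from a list of 15, 1 was lower, the lyase gene *rglA* (-2.53, SE 0.78, adjusted p = 0.014), a call lost without reference replicate 2 (adjusted p = 0.061) or deletion replicate 1 (0.092). Fold sizes depended on the deletion replicates. *pgaX* had 209 and 9 reads and *pgxB* 109 and 3, and without replicate 1 they changed by -8.71 and -8.47, *pgxC* by -5.77 and *gaaB* by -5.83. Without replicate 2 the values were -4.14 for *pgaX*, -3.30 for *pgxB*, -4.20 for *pgxC*, -3.18 for *rglA* and 3.4 for *abnC*.

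In edgeR's test 4969 of 10003 genes (49.7%) were called on GA, 2621 higher and 2348 lower (52.7% higher, from 49.7% with only the libraries compared to 57.7% with total count scaling). Adjusted over the list alone, the counts were the same for all 4 lists. The GA list stood below other genes in camera (adjusted p = 4.4e-09, and 0.019 with an estimated correlation). The homogalacturonan list did so with the preset correlation (adjusted p = 8.9e-05) and lost the call with an estimated correlation (adjusted p = 0.086). The other lists were not called, at adjusted p = 0.57 for rhamnogalacturonan and xylogalacturonan and 0.27 for side chains. None of the 10 highest or 10 lowest genes on GA had a name here. The named genes come largely from publications on this regulator. Here and in the conditions below, list tests and counts of named genes are therefore not independent evidence of direction.

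On SBP at 2 h the same question was put for a polymer. All 5 GA genes were again lower: *gaaB* fell from 11723 ± 797 to 114 ± 87 FPKM (log2 fold change -6.76, SE 0.52, adjusted p = 5e-07), *gaaC* changed by -6.33 (SE 0.43), *gatA* by -6.14 (SE 0.41), *gaaA* by -6.09 (SE 0.36) and *gaaD* by -1.56 (SE 0.34). The *gaaD* level was 3807 ± 732 FPKM in the deletion strain against 11412 ± 231 in the reference. *gaaX* changed by -5.43 (SE 0.25). Of 9 homogalacturonan enzymes 7 were lower and 0 higher, 8 when adjusted over the list alone, led by *pgaX* (-7.50, SE 1.02), *pgxB* (-7.34, SE 0.95), *pgxC* (-6.07, SE 0.39) and *pmeA* (-3.65, SE 0.58). Of 4 side chain enzymes 3 were lower, *lacC* (-4.65, SE 0.31), *lacB* (-3.31, SE 0.29) and *abfC* (-2.19, SE 0.27), and 1 was higher only when adjusted over the list alone. Of 3 rhamnogalacturonan and xylogalacturonan enzymes 2 were lower: *rglA*, at 0 reads in the deletion strain and at least 5.3-fold lower, and the xylogalacturonan hydrolase gene *xghA* (-2.61, SE 0.66). The *rglA* call was lost without reference replicate 2 or deletion replicate 1 (adjusted p = 0.079 and 0.081), and the *xghA* call without reference replicate 1 or deletion replicate 2 (adjusted p from 0.072 to 0.13) and with limma on log2(FPKM + 0.1) (0.073). Without deletion replicate 2 the changes were -10.64 for *pgaX*, -8.49 for *pgxB*, -7.67 for *gaaB*, -6.85 for *gatA* and -4.35 for *pmeA*. Without deletion replicate 1 they were -6.59 for *pgaX*, -6.71 for *pgxB* and -3.29 for *xghA*.

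On SBP at 2 h, 1456 genes (14.6%) were called, 735 higher and 721 lower. This count moved with single libraries, to 592 without reference replicate 1, 572 without reference replicate 2 and 634 without deletion replicate 1, and a fit of only these 4 libraries called 736. Without deletion replicate 2 it was 1803. The share of calls that were higher, 50.5%, turned as well: 39%, 40% and 39.7% without the first 3 libraries, 57.3% without the last and 37.8% in the fit of only these 4. It was 42.1% with RLE scaling, 43.9% with DESeq2, 55.5% with total count scaling, and 54.9% and 56.1% with limma on log2(FPKM + 1) and log2(FPKM + 0.1). In camera the GA list (adjusted p = 4e-29, and 0.0017 with an estimated correlation), the homogalacturonan list (8e-15 and 0.0094) and the side chain list (1.4e-09 and 0.0017) stood below other genes. The rhamnogalacturonan and xylogalacturonan list was called with the preset correlation (adjusted p = 0.039) and not with an estimated correlation (adjusted p = 0.089). Of the 10 lowest genes 5 had names, *gaaR*, *pgaX*, *pgxB*, *gaaB* and *gaaC*, and of the 10 highest 0. As the names stem largely from work on this regulator, neither these counts nor the list tests are independent evidence of direction.

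On SBP at 8 h the GA genes were still lower in the deletion strain, 5 of 5. The changes were -6.27 for *gaaC* (SE 0.43), -5.61 for *gatA* (SE 0.40), -5.39 for *gaaB* (SE 0.48), -5.14 for *gaaA* (SE 0.35) and -2.39 for *gaaD* (SE 0.35, adjusted p = 4.1e-05), and *gaaX* changed by -4.95 (SE 0.25). All 9 homogalacturonan enzymes analysed, from a list of 20, were lower. The pectin lyase gene *pelA* fell from 862 ± 182 to 9.02 ± 0.44 FPKM (log2 fold change -6.57, SE 0.40, adjusted p = 8.1e-09), followed by *pgxB* (-5.83, SE 0.85), *pgaX* (-5.73, SE 0.92) and *pgxC* (-5.51, SE 0.38). Other pectin enzymes went both ways: *lacC* (-5.20, SE 0.32), *lacB* (-2.24, SE 0.28) and the exorhamnogalacturonase gene *rgxB* (-2.77, SE 0.64) fell, while *abnC* (3.55, SE 0.43) and *xghA* (2.01, SE 0.48) rose, *xghA* from 18.5 ± 5.66 to 74.1 ± 12.3 FPKM. The *rgxB* call was lost without reference replicate 2 (-1.78, adjusted p = 0.059) and the *xghA* call with limma on log2(FPKM + 0.1) (0.085). Without reference replicate 1 *rgxB* changed by -3.38. Without deletion replicate 2 the change was -3.94 for *rgxB* and -6.93 for *gaaC*, and without deletion replicate 1 -6.59 for *pgxB* and -6.26 for *pgxC*.

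At 8 h 4378 genes (43.8%) were called, 2240 higher and 2138 lower (51.2% higher, and 49.2% without reference replicate 1), and list counts adjusted over the list alone were the same. The GA list (adjusted p = 1.1e-09, and 0.019 with an estimated correlation) and the homogalacturonan list (4.3e-09 and 0.019) stood below other genes in camera. The side chain list and the rhamnogalacturonan and xylogalacturonan list did not, at adjusted p = 0.12 and 0.71. Only *pelA* had a name among the 10 lowest genes, and 0 did among the 10 highest.

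By 24 h on SBP the GA genes were lower than at 2 h in both strains. In the deletion strain *gatA* (log2 fold change -5.17, SE 0.45), *gaaC* (-4.13, SE 0.40), *gaaA* (-3.35, SE 0.33) and *gaaB* (-1.86, SE 0.42, adjusted p = 0.0031) were still lower than in the reference. *gaaD* had a change of -0.80 (SE 0.33, adjusted p = 0.089) and was not called; it passed when adjusted over the list alone (0.03) and without reference replicate 1 (-1.24, 0.011), but was -0.15 without reference replicate 2 (0.81). *gaaX* changed by -3.62 (SE 0.24). Of 9 homogalacturonan enzymes 6 were lower, 8 when adjusted over the list alone, among them *pgxB* (-6.94, SE 0.93), the endopolygalacturonase gene *pgaC* (-5.51, SE 0.90), *pgaX* (-4.93, SE 0.94) and the methylesterase gene *pmeC* (-4.18, SE 0.54). *rgxB* fell from 117 ± 40.3 to 0.50 ± 0.13 FPKM (-7.99, SE 0.63, adjusted p = 1.3e-07), the 1 called gene among 3 of its list. Of 4 side chain enzymes 3 were lower: *lacC* (-5.53, SE 0.34), *abfC* (-1.59, SE 0.27) and *lacB* (-0.93, SE 0.29), the last lost without reference replicate 1 or deletion replicate 1 (adjusted p = 0.25 for each) and in a fit of only the libraries compared (0.077). *pgaC*, at 0 and 4 reads in the deletion strain, changed by -3.87 and -6.26 without reference replicate 1 or 2 and by -4.52 without deletion replicate 1. *pmeC* changed by -3.08 and -4.80 without reference replicate 1 or 2, and *pgxB* by -7.95 without deletion replicate 1.

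At 24 h 2847 genes (28.5%) were called, 1262 higher and 1585 lower, and 1722 without deletion replicate 1. The share of calls that were higher was 44.3%, against 57.5% with total count scaling and 58% and 56.7% with limma on log2(FPKM + 1) and log2(FPKM + 0.1), so the balance of directions turned with the scaling. The GA list stood below other genes (camera adjusted p = 2.7e-06, and 0.045 with an estimated correlation), as did side chain enzymes (0.00098 and 0.019). The homogalacturonan call (adjusted p = 0.00056) was lost with an estimated correlation (adjusted p = 0.11), and the rhamnogalacturonan and xylogalacturonan list had an adjusted p of 0.095. *gaaR* was the 1 named gene among the 10 lowest, and the 10 highest held 0.

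**Figure D2:**
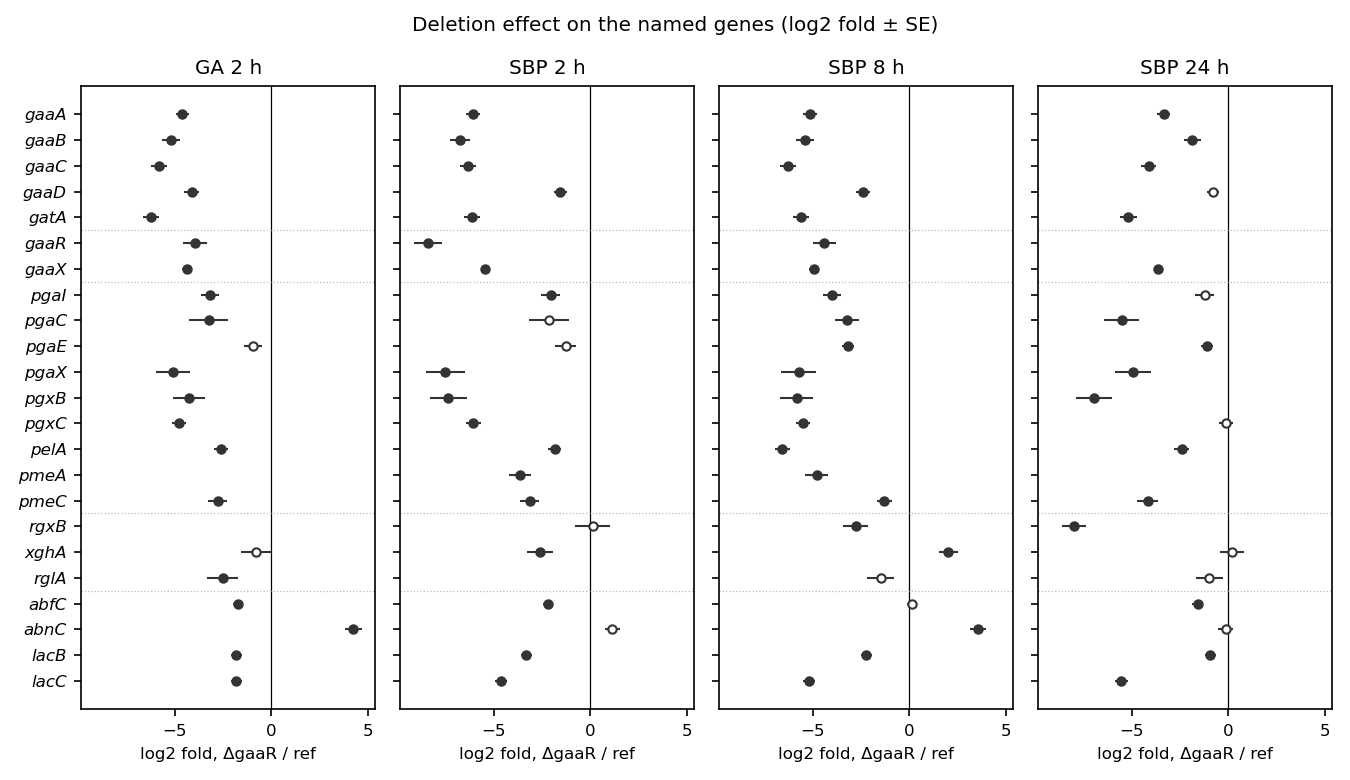
Log2 fold changes of the deletion strain against the reference for the 23 named genes, 1 panel per condition, with bars for the SE. Filled points passed an adjusted p of 0.05; genes with 3 or fewer reads in the deletion libraries of a condition are not drawn. The 5 GA genes, at the top, lie left of 0 in all 4 panels, *gaaD* at 24 h without passing the test.

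How far the 4 sets of calls coincided was tested over the 10003 genes, with no library shared between comparisons. All sets came from the same fit, however, so the spread estimate of each gene was common to them. Genes are also not independent replicates. The numbers for independent lists are therefore only a rough standard, and the p-values can overstate the certainty. Lower in all 4 conditions were 78 genes, against 5.73 for independent lists, and 12 of these had names: *gaaR*, *gaaX*, *gaaA*, *gaaB*, *gaaC*, *gatA*, *pgaX*, *pgxB*, *pelA*, *pmeC*, *lacB* and *lacC*. Among calls of at least 2-fold there were 57 such genes against 1.76, and 11 had names, *lacB* no longer among them. Higher in all 4 were 60 genes against 5.44, and 0 of them had names. Since the names come largely from publications on this regulator, their uneven share between the directions is not independent evidence. The GA and 8 h SBP comparisons shared the most, 1179 lower genes against 502 for independent lists (odds ratio 7.04) and 1287 higher genes against 587. Genes lower on GA and at 24 h numbered 343 against 372 (Fisher's exact test, adjusted p = 0.067), and genes higher on SBP at 2 and 24 h 106 against 92.7 (adjusted p = 0.13); neither overlap passed the test, though the latter did among calls of at least 2-fold (64 against 46.2, adjusted p = 0.0075) and not with DESeq2 (0.11). Opposite directions were tested after the data were seen, in 12 tests. Shared more often than for independent lists were 178 genes against 91 (lower on SBP at 2 h, higher at 24 h, adjusted p = 1.3e-19), 527 against 415 (lower at 24 h, higher on GA, 3e-11) and 159 against 116 (lower at 24 h, higher on SBP at 2 h, 2.7e-05). Shared less often were 92 against 526 (lower on GA, higher at 8 h, adjusted p = 2.4e-169), 176 against 560 (the reverse, 1.2e-118), 103 against 161 (lower on SBP at 2 h, higher at 8 h, 3.6e-08), 115 against 157 (the reverse, 8.4e-05) and 194 against 270 (lower at 8 h, higher at 24 h, 2.6e-08). The other 4 did not pass (adjusted p from 0.13 to 0.49).

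**Figure D3:**
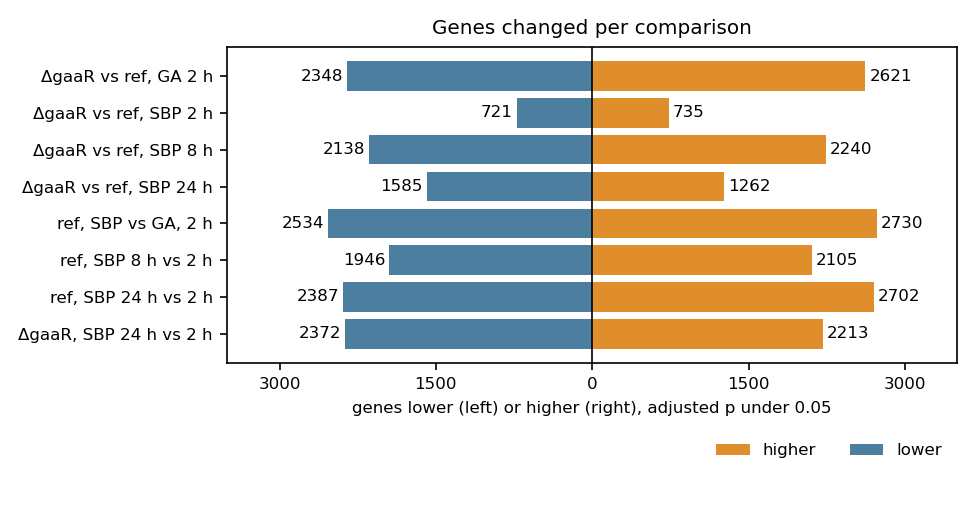
Number of genes called at an adjusted p under 0.05 in 8 comparisons, with lower genes drawn to the left and higher genes to the right of 0. The deletion on SBP at 2 h has the fewest, 721 lower and 735 higher.

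In the reference strain, SBP was compared with GA at 2 h. Of the 5 GA genes 4 did not pass, which does not show equal levels, and no list test was run here: *gaaB* (log2 fold change 0.00, SE 0.40, adjusted p = 1), *gatA* (-0.11, SE 0.32, adjusted p = 0.79), *gaaC* (0.32, SE 0.34, adjusted p = 0.46) and *gaaD* (0.45, SE 0.33, adjusted p = 0.28). *gaaA* passed at 0.79 (SE 0.29, adjusted p = 0.032), but not when adjusted over the list alone, nor without any 1 of the 4 libraries (adjusted p from 0.072 to 0.13). *gaaR* was higher on SBP (3.04, SE 0.52), as was *gaaX* (0.97, SE 0.21). All 4 side chain enzymes analysed, from a list of 11, were higher, *abfC* (3.53, SE 0.28), *lacC* (3.31, SE 0.29), *lacB* (1.77, SE 0.27) and *abnC* (1.09, SE 0.39). Of 9 homogalacturonan enzymes 1 was lower, the endopolygalacturonase gene *pgaI* (-1.64, SE 0.41), and 2 were higher, *pmeA* (1.24, SE 0.47) and *pgxC* (0.99, SE 0.29), and *xghA* was higher too (1.77, SE 0.62). Adjusted over the list alone, 1 homogalacturonan enzyme was lower and 1 higher. Calls were lost without GA replicate 1, GA replicate 2 or SBP replicate 2 for *pmeA* (adjusted p from 0.098 to 0.21) and *abnC* (0.07 to 0.18), without GA replicate 1, GA replicate 2 or SBP replicate 1 for *xghA* (0.091 to 0.19), and without GA replicate 1 or SBP replicate 1 for *pgxC* (0.055 to 0.07). With limma on log2(FPKM + 0.1) the calls of *pmeA*, *xghA* and *pgxC* were lost (adjusted p = 0.23, 0.12 and 0.088). In all 5264 genes were called, 2730 higher and 2534 lower (51.9% higher, and 49.2% with only the libraries compared).

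Change over time on SBP was then followed in the reference strain. Between 2 and 8 h 5 of 9 homogalacturonan enzymes rose and 4 were not called, without a test of the list for this comparison. The rise was led by the endopolygalacturonase gene *pgaE* from 3.16 ± 0.11 to 178 ± 12.6 FPKM (log2 fold change 5.68, SE 0.38, adjusted p = 8.1e-08), *pelA* (4.28, SE 0.35), *pgaC* (4.19, SE 0.68) and *pgaI* (2.38, SE 0.42), and *rgxB* rose (3.02, SE 0.66). *abfC* (-2.58, SE 0.27), *lacB* (-2.21, SE 0.28) and *abnC* (-1.52, SE 0.40) fell, as did *gaaR* (-2.02, SE 0.49), *gaaX* (-0.67, SE 0.21) and 1 GA gene, *gaaA* (-0.87, SE 0.29). *gaaB*, *gaaC*, *gaaD* and *gatA* had changes of -0.41, -0.40, -0.72 and 0.21 (SE 0.40, 0.34, 0.33 and 0.32) and were not called, but *gaaD* passed with DESeq2 (adjusted p = 0.045) and with only the libraries compared (0.0018), and *gaaC* with the latter (0.046). Calls were lost for *gaaA* without any 1 of the 4 libraries (adjusted p from 0.067 to 0.15), for *gaaX* without any but 2 h replicate 2 (0.059 to 0.13), for *abnC* without 2 h replicate 2 or 8 h replicate 1 (0.058 to 0.081) and for *gaaR* without 8 h replicate 1 (0.051). The *gaaR* call was also lost with DESeq2 (adjusted p = 0.2) and limma on log2(FPKM + 0.1) (0.23). These fits take the spread from all 16 libraries. Deletion replicates of *gaaR* lay far apart at 2 h, at 30 and 1 reads on GA and 0 and 12 on SBP. In the reference *gaaR* stood at 224 ± 12.9 FPKM at 2 h and 60.5 ± 3.38 at 8 h. Whether the deletion libraries ended the *gaaR* call was not tested. The calls of *gaaX* and *gaaA* were lost with total count scaling (-0.54 and -0.73, adjusted p = 0.077 and 0.069). They were also lost with limma on log2(FPKM + 1) and log2(FPKM + 0.1) (adjusted p = 0.077 and 0.087 for *gaaX*, 0.078 and 0.087 for *gaaA*). *pgaC*, at 20 and 6 reads at 2 h, changed by 5.36 and 3.52 without 2 h replicate 1 or 2, and *rgxB* by 3.62 and 2.02 without 8 h replicate 1 or 2. In all 4051 genes were called, 2105 higher and 1946 lower. This is 52% higher, against 60.1% with total count scaling and 59.4% and 59.1% with limma on log2(FPKM + 1) and log2(FPKM + 0.1).

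Between 2 and 24 h in the reference strain all 5 GA genes fell, *gaaB* from 11723 ± 797 to 209 ± 64.4 FPKM (log2 fold change -6.01, SE 0.50, adjusted p = 1.1e-07), *gaaA* by -4.64 (SE 0.34), *gaaD* by -4.40 (SE 0.38), *gatA* by -4.08 (SE 0.37) and *gaaC* by -4.00 (SE 0.39). *gaaR* (-1.54, SE 0.48) and *gaaX* (-2.63, SE 0.22) fell. Of 9 homogalacturonan enzymes 5 fell and 2 rose, with *pgxC* at -4.90 (SE 0.35), *pmeA* at -4.31 (SE 0.59), *pgaX* at -3.03 (SE 0.80) and *pgaE* at 2.97 (SE 0.37). *rgxB* rose by 6.85 (SE 0.59) and *abnC* by 3.12 (SE 0.41), while *lacB* (-5.34, SE 0.32), *abfC* (-4.83, SE 0.30), *lacC* (-1.59, SE 0.27) and *xghA* (-1.72, SE 0.58) fell. Calls were lost without 2 h replicate 1 or 24 h replicate 1 for *gaaR* (adjusted p from 0.064 to 0.069) and without 2 h replicate 1 or 24 h replicate 2 for *xghA* (0.16 to 0.19). The *gaaR* call was also lost with DESeq2 (adjusted p = 0.32) and limma on log2(FPKM + 0.1) (0.37), the *pgaX* call with the latter (0.083), and the *xghA* call with limma on log2(FPKM + 1) and log2(FPKM + 0.1) (0.054 and 0.15). These fits again take the spread from all 16 libraries, and in the reference *gaaR* had 832 and 984 reads at 24 h. Without 24 h replicate 1 the changes were -5.28 for *pmeA* and -2.67 for *xghA*, and without 24 h replicate 2 -3.72 for *pmeA* and -5.05 for *gaaD*. In all 5089 genes were called, 53.1% of them higher, against 64.1% with total count scaling and 63.8% and 63.7% with limma on log2(FPKM + 1) and log2(FPKM + 0.1).

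In the deletion strain the 5 GA genes also fell between 2 and 24 h, from levels already low for 4 of them: *gaaD* changed by -3.63 (SE 0.37), *gatA* by -3.11 (SE 0.45), *gaaA* by -1.90 (SE 0.31), *gaaC* by -1.80 (SE 0.37) and *gaaB* by -1.11 (SE 0.41). *gaaX* changed by -0.83 (SE 0.23), and *gaaR*, at 0 and 12 reads at 2 h and 0 and 0 at 24 h, is given no fold. *abfC* (-4.23, SE 0.30), *lacB* (-2.96, SE 0.30), *lacC* (-2.47, SE 0.32) and *pelA* (-1.45, SE 0.40) fell, and *pgaE* (3.12, SE 0.45) and *abnC* (1.85, SE 0.39) rose. *rglA* was at 0 reads at 2 h and had 2.30 ± 0.11 FPKM at 24 h, and *pmeA* had 1 read over both 24 h libraries. Calls were lost for *gaaB* without 2 h replicate 2, 24 h replicate 1 or 24 h replicate 2 (adjusted p from 0.13 to 0.7), for *gaaX* without 24 h replicate 1 (0.09), for *pelA* without 2 h replicate 1 or 24 h replicate 1 (0.068 to 0.1) and for *pmeA* without 2 h replicate 2 or 24 h replicate 1 (0.13 to 0.15). The *gaaB* call was lost as well with RLE scaling (-1.03, adjusted p = 0.053), total count scaling (-0.79, 0.16), limma on log2(FPKM + 1) and log2(FPKM + 0.1) (-0.54 and -0.55, 0.37 and 0.38) and only the libraries compared (-1.05, 0.088). That of *gaaX* was lost with total count scaling (-0.44, adjusted p = 0.16) and both limma fits (-0.42 and -0.44, 0.15 for each), and that of *pmeA* with limma on log2(FPKM + 1) (0.062). Without the 2 h deletion libraries with most *gaaR* reads, a fit added after the data were seen, *gaaB* changed by -0.21 (adjusted p = 0.56), and *gatA* by -2.39 without 2 h replicate 2. In all 4585 genes were called, 48.3% of them higher, against 53.6% with RLE scaling, 52.8% with DESeq2, 54.3% with only the libraries compared, 52.2% without 24 h replicate 1, 70% with total count scaling and 70.1% and 69.4% with limma on log2(FPKM + 1) and log2(FPKM + 0.1), so here too the balance turned with the scaling.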

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

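All tests of explanations in this part were chosen after the results were seen; the tests of differences between conditions were fixed before the data were examined.

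The effect of the deletion differed between SBP and GA at 2 h for 3733 genes in edgeR's interaction test. Relative to GA, the fall on SBP was larger for *gaaA* (difference of log2 fold changes -1.49, SE 0.42, adjusted p = 0.01), *lacB* (-1.49, SE 0.38), *lacC* (-2.83, SE 0.40), *gaaX* (-1.07, SE 0.31), *gaaB* (-1.56, SE 0.57), *pgxB* (-3.07, SE 1.15) and *gaaR* (-4.44, SE 1.05). It was smaller for *gaaD* (2.57, SE 0.47, adjusted p = 0.00048). The rise of *abnC* on GA was not seen to the same extent on SBP (-3.09, SE 0.56). Several of these calls were lost in other fits. *gaaR* was lost without GA deletion replicate 1 (-0.61, adjusted p = 0.9), and *gaaX* without that library or SBP reference replicate 1 (adjusted p from 0.052 to 0.06). *gaaB* (adjusted p from 0.073 to 0.21) and *pgxB* (0.067 to 0.56) were lost without any 1 of the 4 reference libraries, GA deletion replicate 1 or SBP deletion replicate 1, and *pgxB* turned to 1.13 without GA deletion replicate 1. Without SBP deletion replicate 2 *gaaB* differed by -2.47 and *pgxB* by -4.23, and no *gaaR* read was left there. With GA deletion replicate 1 left out instead, *gaaB* differed by -0.93. Without SBP deletion replicate 1 *gaaR* differed by -3.47, and without GA deletion replicate 2 *gaaR* by -5.41, *pgxB* by -4.04 and *abnC* by -2.26. The *pgxB* call was lost too with DESeq2 (adjusted p = 0.13), limma on log2(FPKM + 1) and log2(FPKM + 0.1) (0.24 and 0.43), only the libraries compared (0.081) and adjustment over the list alone (0.14). That of *gaaB* was lost with the same 2 limma fits (adjusted p = 0.053 and 0.06) and only the libraries compared (0.1), and that of *gaaR* with limma on log2(FPKM + 0.1) (0.06). An added fit without the 2 h deletion libraries with most *gaaR* reads, chosen after the data were seen, gave -0.02 for *pgxB* (adjusted p = 1), -6.31 for *gaaR* (0.092) and -0.90 for *gaaX* (0.051).

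Between 8 and 2 h on SBP the deletion effect differed for 2796 genes, 48% of them positive, against 54.1% with RLE scaling, 53.8% with DESeq2, 50.2% with only the libraries compared, and 50.3%, 51.3%, 50.6% and 53.7% without reference 2 h replicate 1, deletion 2 h replicate 1, reference 8 h replicate 2 or deletion 8 h replicate 2. Relative to the reference, *pelA* was lowered more at 8 h (-4.72, SE 0.50, adjusted p = 8.1e-06), as were *pgaI* (-1.95, SE 0.68) and *pgaE* (-1.91, SE 0.67). In the reference they rose from 40.6, 18.8 and 3.16 to 862, 106 and 178 FPKM. In the deletion strain they stood at 11.1, 4.38 and 1.35 at 2 h and at 9.02, 6.59 and 19.7 at 8 h. At 2 h *pgaE* had only 13 and 15 reads in the reference and 4 and 8 in the deletion strain. The difference was positive for *gaaR* (4.0, SE 0.99), *xghA* (4.62, SE 0.81), *abnC* (2.42, SE 0.55), *abfC* (2.33, SE 0.37), *pmeC* (1.84, SE 0.61) and *lacB* (1.07, SE 0.38). Of 8 libraries, leaving out any 1 of 7 ended the calls of *pgaI* (all but deletion 2 h replicate 2, adjusted p from 0.063 to 0.25) and *lacB* (all but deletion 2 h replicate 1, 0.088 to 0.14). Any 1 of 6 ended those of *pgaE* (all but deletion 2 h replicate 1 and deletion 8 h replicate 1, 0.064 to 0.33) and *pmeC* (all but reference 2 h replicate 2 and deletion 2 h replicate 2, 0.054 to 0.15). The *gaaR* call was lost with DESeq2 (4.11, adjusted p = 0.085), those of *pgaI* and *pgaE* with RLE scaling (0.053 each), that of *pgaI* with limma on log2(FPKM + 0.1) (0.064) and that of *pmeC* with limma on log2(FPKM + 1) and log2(FPKM + 0.1) (0.066 and 0.068). Without deletion 2 h replicate 1 *gaaR* differed by 3.02 and *xghA* by 5.30, and without deletion 2 h replicate 2 *pmeC* by 2.43. In the added fit *pgaE* (adjusted p = 0.34) and *lacB* (0.087) were not called.

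Between 24 and 2 h on SBP the deletion effect differed for 2396 genes, and for 1509 without deletion 24 h replicate 1. Of all calls 41.7% were positive, against 50.8% with total count scaling and 53.9% and 52.4% with limma on log2(FPKM + 1) and log2(FPKM + 0.1). The effect was smaller at 24 h for *gaaB* (4.90, SE 0.60, adjusted p = 2.8e-05), *gaaA* (2.74, SE 0.43), *gaaC* (2.20, SE 0.50), *gaaX* (1.81, SE 0.31), *pgxC* (5.93, SE 0.52) and *lacB* (2.38, SE 0.40). At 24 h *pgxC* stood at 7.9 ± 0.04 FPKM in the reference and 8.21 ± 1.53 in the deletion strain, so little could be lowered there. *xghA* differed by 2.82 (SE 0.91), a call lost without reference 2 h replicate 1, deletion 2 h replicate 2, reference 24 h replicate 2 or deletion 24 h replicate 2 (adjusted p from 0.092 to 0.13) or with limma on log2(FPKM + 0.1) (0.096). It was 3.50 without deletion 2 h replicate 1 and 3.76 without reference 24 h replicate 1. *rgxB* differed by -8.09 (SE 1.30), and by -8.70 and -6.99 without deletion 2 h replicate 1 or 2. At 2 h it had only 3 and 5 reads in the reference and 2 and 7 in the deletion strain, so a fall could hardly show there. *gaaB* differed by 5.80 without deletion 2 h replicate 2. The fitted value of *rglA*, 6.11 (SE 2.12), rests on 0 reads in the deletion strain at 2 h and is no measure of size; its call was lost without any 1 library but the 2 reference libraries at 24 h (adjusted p from 0.065 to 0.14), and with the 10 CPM filter (0.052), limma on log2(FPKM + 1) (0.14), only the libraries compared (0.11) and the added fit (0.11).

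Reads of *gaaR* appeared in 5 of 8 deletion libraries, and they move the differences above: 30 and 1 on GA, 0 and 12 on SBP at 2 h, and 24 and 24 at 8 h. A remnant of *gaaR* transcribed in the deletion strain would leave reads in all 8 libraries, yet 3 libraries held 0 where the reference libraries of their condition held over 100 reads. Admixture from reference libraries of the same condition would keep every gene above its share, but 16 to 75 genes lay below it in each of the 3 libraries tested, GA replicate 1 and both at 8 h (2259 to 4469 genes testable), *gaaC* and *gaaB* among them; GA replicate 2, with 1 read, was not tested. Reads from reference libraries on SBP at 2 h remain a candidate source for these 3. Shares of 1.76%, 1.35% and 1.2% would bring the *gaaR* reads. The test used the lower 95% bounds of these shares, 1.18%, 0.86% and 0.77%, which is lenient to that source. At these bounds 1, 1 and 0 genes lay below (718, 513 and 513 testable). Each of 4 deletion libraries with 0 or 1 *gaaR* reads was set to each of the 3 bounds, *gaaR* left out. At a single bound 3 to 17 genes lay below. The test used sums over the 3 bounds, 2 against 11 to 43, in which a gene of a control library can count more than once. For SBP replicate 2 at 2 h the share was 0.64% and its lower bound 0.33%, with 169 testable genes and 0 below. There that source cannot be told apart from others, as the same 4 libraries gave 0 to 5. The limits for these tests (at most 3 genes, at least 10 in each of the 4 libraries) were set on sums and after the counts had been seen. SBP deletion replicate 1 at 2 h gave 4, 4 and 3 at the single bounds, so only its sum reached the limit. The evidence is therefore weak.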

How the results depend on the processing

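Counts of called genes stayed within 1.5 times the reported count in all 11 comparisons under the alternatives fixed beforehand, with these exceptions. For the deletion on SBP at 2 h the count of 1456 fell to 736 with only the libraries compared, and ranged from 572 to 1803 with 1 library left out; the added fit without the 2 h deletion libraries holding most *gaaR* reads, chosen after seeing the data, gave 2187. Leaving out 1 library gave 1722 to 2405 for the deletion at 24 h and 1509 to 2659 for the difference of its effect from 2 h, the lowest without deletion 24 h replicate 1 in both. The lone library of a group was then assumed to vary like the other groups. Among list tests, an estimated correlation ended the calls of homogalacturonan enzymes on GA (0.086) and at 24 h (0.11) and of rhamnogalacturonan and xylogalacturonan enzymes on SBP at 2 h (0.089), while fry, which asks only whether a list moves one way, called side chain enzymes on GA (0.001) and at 8 h (0.00016) and the rhamnogalacturonan list at 24 h (5e-04). Of 2026 values for 142 called gene results over all settings, 1870 kept direction and call, 155 lost the call and 1 reversed, *pgxB* in the difference of SBP from GA (1.13 without GA deletion replicate 1, to -4.23 without SBP deletion replicate 2). Of 130 values for 10 uncalled results, 113 were the same, 7 passed the threshold and 10 changed sign. Of these 8 were *gaaB* in SBP against GA, a value at 0.00: 0.04 with total count scaling, 0 with no low count filter, 0.01 with the 10 CPM filter, 0.05 with both limma fits, 0.01 with the replicate block, and 0.09 and 0.06 without reference GA or SBP replicate 2 (lowest with 1 library left out -0.08). The other 2 were *gaaR* at 24 against 2 h in the deletion strain, at 0 without deletion 2 h replicate 2 and in the added fit, where all reads are gone; its fitted value, -6.66 at the lowest without deletion 2 h replicate 1, is no measure of size. Leaving out 1 library moved the fold of 42 of 152 gene results by over 1.5 times, 28 of them with no change of call. The cause of the other changes was not tested. Replicate numbers do not pair the samples: 28 correlations of deviations between groups ran from -0.428 to 0.333, with 4 above 0.1. The largest in size lay between deletion groups. These were -0.428 (GA, SBP 2 h), 0.333 (GA, SBP 24 h) and -0.316 (SBP 2 h, SBP 24 h). A negative value means that differently numbered libraries deviated together, which a block by replicate number cannot take up. With the replicate block 4977 genes were called on GA and 1461 on SBP at 2 h, and the rhamnogalacturonan list at 24 h passed (0.029); of the gene calls, those of *pgxB* (0.064) in the difference of SBP from GA, *pgaE* (0.052) and *lacB* (0.053) in that of 8 from 2 h and *rglA* (0.058) in that of 24 from 2 h did not pass. With 3203011 to 4574019 reads per library, 33% to 46% of simulated 2-fold changes were recovered in the deletion comparisons. Far fewer genes were changed in the simulation than were called in the data, so these shares need not hold for the data.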

Other observations

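All tests in this part were chosen after the results were seen.

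Outside the named genes, a pair of genes with adjacent locus tags rose at 2 h in the deletion strain. NRRL3_03213 went from 2.09 ± 0.35 to 458 ± 24.3 FPKM on GA (log2 fold change 7.67, SE 0.35, edgeR adjusted p = 3.71e-10) and from 6.22 ± 2.24 to 132 ± 49.9 on SBP. NRRL3_03212 went from 7.06 ± 0.03 to 722 ± 144 FPKM on GA (6.55, SE 0.31) and from 16.7 ± 5.93 to 310 ± 113 on SBP. At 8 h neither was called, with changes of -0.09 and -0.59 (SE 0.34 and 0.29), and at 24 h neither was, at means of 0.30 FPKM or less in both strains. Both were singled out after their values were seen, and no table used here gives their function.

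A run of 24 tested genes with consecutive locus tags, with 2 untested tags between them, was lower by at least 2-fold in the deletion strain on SBP at 24 h (median log2 fold change -7.82). Its median level was 174 FPKM in the reference and 1.25 in the deletion strain, against 0.22 in the reference at 8 h. Within it NRRL3_00158 had 172 ± 109 against 0.22 ± 0.31 FPKM, and NRRL3_00138 42.6 ± 24.4 against 0.04 ± 0.05, so the reference replicates lay far apart. On GA at 2 h 11 of the 24 were higher in the deletion strain by at least 2-fold. The longest runs in the other deletion comparisons and directions held 4 to 12 genes.

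Chance placement is argued against by the run's length of 24, where 10000 random placements of the 1233 calls gave a longest run of 4.08 on average and at most 9 (permutation p = 0.0001, the smallest they can give); over the 8 comparisons and directions p ran from 0.0001 to 0.063, and a count of neighbouring pairs was above chance in all 8, so it does not single out this run. Loss of the whole stretch from the deletion strain is argued against by 7 of its genes, which reached 10 FPKM in both deletion libraries on GA. A stricter form of that test, in which 80% of the genes had to exceed 3 reads in both libraries of a deletion group, was narrowly missed at 19 of 24 (79.2%) and was then replaced, so the choice of test favoured this outcome. Loss of a part of it cannot be told apart from silence, since 11 genes had no deletion group in which both libraries exceeded the reads that admixture of reference libraries could bring, while 13 did; all but 5 exceeded 3 reads in both libraries of a group, yet *gaaR* itself left up to 30, and an earlier bound of 10 FPKM had left 15 genes open. Reads shared between near-identical copies could give fractional counts, and 0% of the run's listed counts were not whole. Of all listed counts only 0.3% were not whole, and the role of each processing tool is not known. This test therefore cannot decide about shared reads. A coordinated difference between the strains at 24 h is a hypothesis that these tests leave open.

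The 4969 calls on GA invite a hypothesis: part of the deletion effect there may be a general difference in growth state. Across 10003 genes, which are not independent replicates, the effect on GA correlated with the difference of 2 h from 8 h on SBP in the reference strain (Pearson r = 0.54, Spearman rho = 0.54), with no library in common, though GaaR activity that changed with time could give this too. Of 7 correlations computed, that with the deletion effect on SBP at 8 h (r = 0.59) would also follow from shared GaaR targets and decides nothing, and those with the deletion effect at 2 and 24 h were 0.20 and 0.01. The rest did not involve the deletion on GA. The deletion effect at 8 h gave r = 0.18 with the reference difference of 24 h from 2 h on SBP. With that of SBP from GA it gave 0.45. The deletion effect at 24 h gave r = -0.04 with the reference difference of 8 h from 2 h. Each of these 2 deletion effects was thus set against only 1 reference change over time, with a weak match at 8 h and none at 24 h. Other intervals were not compared, nor was the effect on GA with the difference of 24 h from 2 h. Whether GA stands apart in this is therefore not shown. Genes higher on GA in the deletion strain and lower at 8 h than at 2 h in the reference numbered 1119 against 509.9 for independent lists, and 1296 against 494.1 in the opposite directions. These lists too share the spread estimate of each gene, so independent lists are only a rough standard. Under 2 other scalings the lowest number of called genes on GA was 4893. The choice among these scalings thus does not account for the number of calls. They moved the median log2 fold change only to 0.02 and 0.2, while 3946 calls were at least 2-fold, so the count could hardly have fallen far. A scaling error common to all of them was not tested. Direct and indirect effects of GaaR were not separated by any test.

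The distance between replicates differed among groups. Of 7053 genes with a mean of at least 50 reads, 8.8% and 10.1% lay over 2-fold apart between the deletion replicates at 2 h on GA and SBP, 5.1% between the reference replicates at 24 h, and 0.9% to 2% in the other groups. On SBP at 2 h in the deletion strain, 97.8% of the genes apart stayed so after removal of a share of reference reads and 53.8% after removal of a trend with coding length, with rank correlations of the difference with coding length from -0.39 to 0.22 over the 8 groups. These are given as values, without an explanation.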
